A study of Rattus norvegicus with 2 samples.

How the data were processed

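RNA from 2 samples of rat neural stem cells, 1 co-cultured with EMSCs and 1 mono-cultured, was labelled with biotin by a whole-transcript protocol and hybridised to 1 array each, per the labels' protocols. The deposited values are log2 levels per transcript cluster, and the submitters' processing notes name RMA, which corrects background, normalizes by quantiles and summarises probes on a log2 scale. The RMA software, its version and the annotation release are not given in the sources used here. The log2 scale was checked from the values, which run from 0.33 to 12.74 with medians of 3.75 (co-cultured) and 3.72 (mono-cultured). Quantile normalization forces similar distributions on the arrays, so a change in total RNA per cell or in most genes at once cannot be seen, and low levels are compressed toward background.

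The table holds 70580 rows, of which 68842 are transcript clusters and 1738 are controls. A table of the platform's annotation gave 1 gene symbol to 23446 probe sets and several to 505, which were left out. The other 44891 transcript clusters are unnamed here. By Entrez ID, 22077 of the named probe sets matched the current rat gene table (GRCr8), and 1 had another symbol there, so the platform's symbols were kept. Probe sets of a gene were averaged, which gave 22093 genes, 1182 of them with more than 1 probe set. A gene was kept if its higher value reached the median of all gene values, 4.97, which left 11849. No detection call was used. The 95th percentile of 1153 negative control probe sets, called the negative control level below, was 6.64, so the limit marks brightness rather than detection. The medians of these controls were 3.39 on the co-cultured and 3.60 on the mono-cultured array. Some genes were not analysed here.

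Scanner output was not used here, and the precision is limited by the number of arrays. Of the spread, only the technical part inside the arrays can be described. Among 475 kept genes with more than 1 bright probe set, the SD of the difference between probe sets of a gene was 0.26. Of these genes 0 had 1 probe set at least 2-fold higher and another at least 2-fold lower. Genes with 1 probe set past 2-fold and another short of it were not counted.

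With 1 array per group no p-value was computed. Genes at or beyond a 2-fold difference (1 on the log2 scale) were counted. For each of 31 gene lists, the median difference of kept members was set against 10000 random lists of the same size, matched on mean level in 20 bins, and a list was said to stand apart if its median lay outside the central 95% of these. Intervals of list medians are 95% bootstrap intervals over members (2000 draws). The lists, the settings and the naming rule were fixed before the data were examined. The rule takes the 15 largest differences in each direction without provisional names, up to 4 members per list with the largest absolute difference, and a fixed set of markers. Exceptions, chosen after their values were seen, are Nt5e, Tmem119, Erbb3, Rgs5 and Kcnj8, and in the closing section Cd68, C1qa and members of gene families. On simulated arrays made for this comparison, with 11563 kept genes and 200 genes changed by 2 on the log2 scale, 100.0% of the changed genes were recovered and 12 unchanged genes passed 2-fold, at a noise SD of 0.3. Of 200 unshifted lists of 20 genes, 3.5% stood apart, and of 50 lists shifted by 0.5, 100.0%. The simulated noise was independent between genes and lay below the SD of the differences of positive (0.44) and negative (0.65) controls. At this noise a change of 2 passes a limit of 1 by construction. These rates check the procedure and do not describe the errors on these arrays.

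Alternatives were median centring, quantile normalization with limma 3.58.1 in R 4.3.3, a loess fit of difference on mean (span 0.4), no filter, brighter filters, other rules for several probe sets, thresholds of 1.5-fold and 4-fold, and the mean in place of the median. Raising dim levels to the limit and leaving out shared list members were added after seeing the data. Other steps used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.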

Results

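Gene expression was measured in rat neural stem cells (NSCs) with a whole-transcript array. The NSCs came from whole brains of day 13.5 embryos and had grown as neurospheres for 10 days. They were then kept for 14 days either on a layer of ectodermal mesenchymal stem cells (EMSCs) from rats that carry green fluorescent protein, or alone. The co-cultured NSCs were recovered by fluorescence-activated sorting, and the mono-cultured NSCs served as control. Each condition is represented by 1 array, so no difference reported here has a replicate check, and no test between the conditions is possible. The comparison addresses which genes differ in NSCs that have grown with EMSCs. Levels are log2 RMA values, and each difference is the co-cultured minus the mono-cultured level. Of 22093 genes with a symbol of their own, 11849 reached the median gene level of 4.97 on at least 1 array and were kept.

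Most mesenchymal and matrix genes had higher levels in the co-cultured than in the mono-cultured NSCs, and most microglia and macrophage genes had lower levels. At a difference of 2-fold or more, 597 kept genes were higher and 657 were lower in co-culture, together 10.6% of the kept genes. The median difference of all kept genes was -0.06 with an SD of 0.79 across genes, and levels on the arrays correlated across these genes with r = 0.78 (genes are not independent replicates). Among the 399 probe sets named as positive controls the differences had an SD of 0.44, with 2 higher and 16 lower by 2-fold or more. Among 1153 negative controls, which are mostly dim, the SD was 0.65, with 38 higher and 110 lower. The share past 2-fold was thus larger among negative controls, and smaller among positive controls, than among kept genes.

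**Figure D1:**
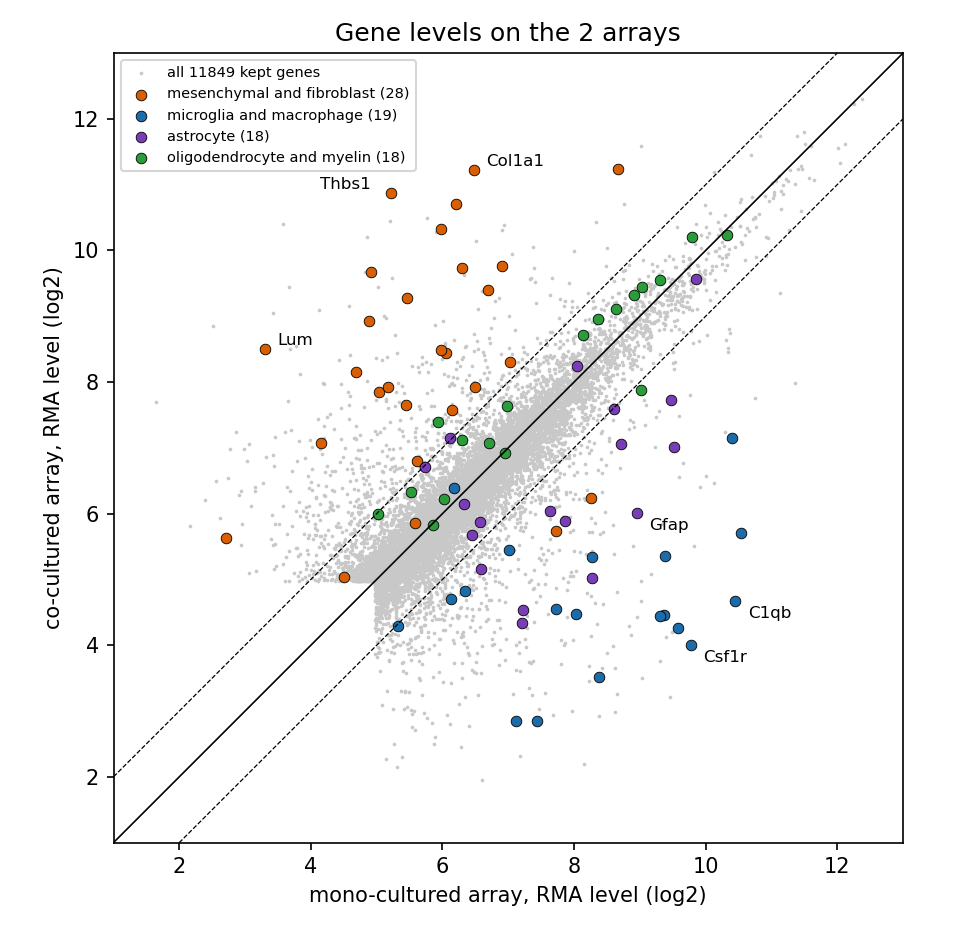
Levels of the 11849 kept genes on the mono-cultured (x) and co-cultured (y) array, both as log2 RMA values, with the members of 4 gene lists in colour; the solid line marks equal levels and the dashed lines a 2-fold difference. Mesenchymal genes such as Col1a1 lie above the upper dashed line and microglia genes such as C1qb lie below the lower one.

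Of the 15 largest differences upward, 5 were in genes of the mesenchymal or matrix lists. Grem1, a secreted antagonist of bone morphogenetic proteins (BMPs), had a level of 10.39 in co-culture and 3.57 in mono-culture, a difference of 6.82. The small leucine-rich proteoglycans Ogn, Aspn and Lum differed by 6.34, 6.06 and 5.20. The matricellular genes Tnn and Thbs1 differed by 5.77 and 5.66, and the collagens Col12a1, Col14a1 and Col1a1 by 5.25, 4.76 and 4.75. Fgf7, a growth factor made by mesenchymal cells, differed by 5.63. The protease inhibitor Slpi differed by 5.35, the lipopolysaccharide-binding protein gene Lbp by 4.98, Tgfbi by 4.85, the transcription factor gene Snai2 by 4.81 and smooth muscle actin Acta2 by 4.76. Downward, the 15 largest differences were in Fcrl2, Clec4a3, C1qb, Csf1r, Clec7a, Fcgr2b, Adgre1, Ms4a6bl1, Mpeg1, Laptm5, Cd53, Pld4, Apobec1, Cd84 and Tyrobp, many of them receptors and signalling genes of myeloid cells. They ranged from -6.24 for Fcrl2 to -4.90 for Tyrobp, and 4 of the 15 genes stand on the microglia and macrophage list. All 30 of these genes had their lower value below 6.64, the 95th percentile of the negative controls, and their higher value above it, so the size of these differences depends on the background. The same holds for the lower value of 517 of the 597 higher genes and 590 of the 657 lower genes.

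Of 28 kept mesenchymal and fibroblast genes, the class of the feeder cells, 24 were at least 2-fold higher in co-culture, 2 were at least 2-fold lower and 2 lay between. The median difference was 2.78 (interquartile range 1.44 to 3.88), and 0 of 10000 random gene lists matched on mean expression had a median as high. Thbs1, Lum, Acta2 and Col1a1 led the list. Col1a1 had a level of 11.23 in co-culture and 6.48 in mono-culture. Thy1, a surface marker of mesenchymal stem cells and of neurons, was 8.48 against 5.97. The exceptions were Eng and Nt5e, which code for the mesenchymal stem cell surface markers CD105 and CD73, with a difference of -2.02 for Eng and levels of 5.73 against 7.73 for Nt5e. On the mono-cultured array 6 of the 28 genes exceeded 6.64, against 23 on the co-cultured array, and 7 of the 28 also stand on another list.

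Of 34 kept genes for other matrix proteins and remodelling enzymes, 25 were at least 2-fold higher and 3 at least 2-fold lower, with a median difference of 2.04 and 0 of 10000 random lists as high. Besides Col12a1, the basement membrane laminin Lama2 differed by 4.29, the elastic fibre gene Fbln5 by 3.77, and Col8a1 was 6.98 against 2.98. Of the 9 kept pericyte and smooth muscle genes, 7 were at least 2-fold higher (median 1.64, 0 of 10000 as high), among them Pdgfrb (2.75), Tpm2 (2.16) and Mcam (1.92). Over all 15 members on the array the median was 0.37, as the 6 dim members, which include Rgs5 and Kcnj8, differed by 0.06 to 0.37, and 6 of the 9 kept genes also stand on another list. Of 13 kept neural crest genes, 7 were at least 2-fold higher and 1, Sox9, was at least 2-fold lower (median 1.09, 0 of 10000 as high). Of these 13 genes 5 exceeded 6.64 in co-culture and 2 in mono-culture, and 6 reached 4.97 in mono-culture, with a median of 0.49. With levels below 4.97 raised to 4.97, an alternative chosen after seeing the data, the list median was 0.72. Snai2 led this list, followed by the low-affinity neurotrophin receptor Ngfr, at 9.58 against 5.24, and by Snai1, which differed by 1.77. Schwann cell genes were mixed, with 5 of 14 at least 2-fold higher, namely Ngfr, Cdh19 (3.37), L1cam (3.14), Egr2 (1.99) and Erbb3 (1.47). Their median of 0.19 lay at percentile 97.59 of matched random lists, but it lay inside their range after median centring (percentile 97.43) and over the 11 members that reached the 75th percentile (percentile 94.40), and was 0.08, at percentile 88.75, over the 12 members that reached 4.97 on both arrays and -0.11, at percentile 39.71, over the 5 members that stand on no other list. The mean of the list was 0.86.

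Microglia and macrophage genes were the lowest list. Of 19 kept members, 18 were at least 2-fold lower in co-culture and 0 were 2-fold higher, with a median difference of -4.02 (interquartile range -4.87 to -2.25) and 0 of 10000 random lists as low. The complement gene C1qb was 4.66 against 10.45. On the mono-cultured array 15 of the 19 genes exceeded 6.64, and on the co-cultured array 1 did. Csf1r, the receptor that microglia need to survive, had a level of 9.78 in mono-culture and a difference of -5.77, Laptm5 differed by -5.32 and Tyrobp by -4.90. Tmem119 was the exception, at 6.39 against 6.18, both below 6.64. With dim levels raised to 4.97 the list median was -3.06. Interferon-stimulated genes were lower as well, with 8 of 20 at least 2-fold lower and 0 higher (median -0.77, 0 of 10000 as low). Mx1, Mx2, Oasl and Irf7 differed by -2.29, -1.91, -1.76 and -1.48, and 6 of the 20 genes exceeded 6.64 in mono-culture and 3 in co-culture.

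Inflammatory genes went both ways. Of 19 kept members, 5 were at least 2-fold higher and 7 at least 2-fold lower. The prostaglandin synthase Ptgs2 was 10.50 against 5.76, Il6, at 5.81 against 2.16 and so below 6.64 on both arrays, differed by 3.65 and Il33 by 3.38, while the chemokine Ccl3 differed by -2.73. The list median of 0.26 lay at percentile 99.47 (0.42 over the 15 members that reached 4.97 on both arrays), and the mean of 0.12 lay inside the range of matched random lists, at percentile 80.64.

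Astrocyte genes were lower in co-culture. Of 18 kept members, 11 were at least 2-fold lower and 1 at least 2-fold higher, with a median of -1.51 (interquartile range -2.37 to -0.39) and 0 of 10000 random lists as low. Gfap, the astrocyte intermediate filament, was 6.00 against 8.96, with the level in co-culture inside the range of the negative controls. Mlc1, Acsbg1 and Ntsr2 differed by -3.26, -2.87 and -2.68, and the calcium-binding protein gene S100b by -0.70. Genes of neural stem cells and progenitors, 17 kept, had a median of -0.997, with 8 at least 2-fold lower and 0 of 10000 random lists as low, and a mean of -0.55. The list split: the glutamate transporter Slc1a3, which is also on the astrocyte list, differed by -2.50 and the forebrain regulator Emx2 by -1.96, whereas the matrix gene Tnc and the Notch target Hes1 differed by 3.41 and 2.60. The stem cell factor Sox2 (8.69 against 8.83), the intermediate filament genes Nes (8.25 against 7.45) and Vim (11.74 against 11.39) lay within 2-fold, and Pax6 was below 4.97 on both arrays.

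The oligodendrocyte lineage differed little beside these lists. Of 18 kept myelin and oligodendrocyte genes, 16 lay within 2-fold and 14 were higher, with a median of 0.41 (interquartile range 0.22 to 0.64) that was matched by 1 of 10000 random lists. Ermn differed by 1.46, Opalin by 0.98 and Mal by 0.82. Mbp, the myelin basic protein gene, was 6.93 against 6.95, and Cldn11 differed by -1.13. Of 13 oligodendrocyte precursor genes, 12 lay within 2-fold, including Olig2 (-0.32), Pdgfra (0.82), Lhfpl3 (-0.69) and Gpr17 (-0.64). The exception was the proteoglycan gene Vcan, which differed by 2.25. Their median of -0.32 lay at percentile 2.34, and their mean of -0.03 lay inside the range of random lists, at percentile 52.87. The median also lay inside that range over the 10 members that reached the 75th percentile (percentile 3.23) and without shared members (percentile 2.61).

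Neuronal genes did not stand apart as a list. Of 19 kept members, 2 were at least 2-fold higher (Thy1 and Reln, the latter by 2.00) and 4 at least 2-fold lower, including Scg2 (-2.26) and Dcx (-1.59), with a median of -0.15 at percentile 18.44 and between -0.37 and -0.06 under the alternatives. Tubb3 and Map2 differed by 0.37 and -0.64. Without the 3 members shared with other lists, Thy1 among them, the median was -0.37, at percentile 0.37; this alternative was chosen after seeing the data. Of 21 synapse and transmitter genes on the array 9 were kept, of which 2 were at least 2-fold lower, Camk2b (-1.31) and Nlgn1 (-1.11), and 0 were 2-fold higher, with Gad1 at -0.65 and Cplx2 at -0.37 (median -0.29, percentile 6.87). Over all 21 the median was -0.03, and with dim levels raised to 4.97 it was -0.13. Endothelial genes (5 kept, median -0.19, percentile 32.16, and -0.83 to -0.08 under the alternatives) included Eng, Pecam1 at -1.48, Cdh5 at 0.96 and Ramp2 at -0.19. Of 22 ependymal and choroid plexus genes on the array, 3 were bright enough: the water channel gene Aqp1 differed by 2.82, Ttr by -0.46 and Foxj1 by -0.38, so that their median (-0.38) and mean (0.66) differ in sign. Over all 22, most of them dim, the median was -0.28, and 0 of 10000 random lists were as low.

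**Figure D2:**
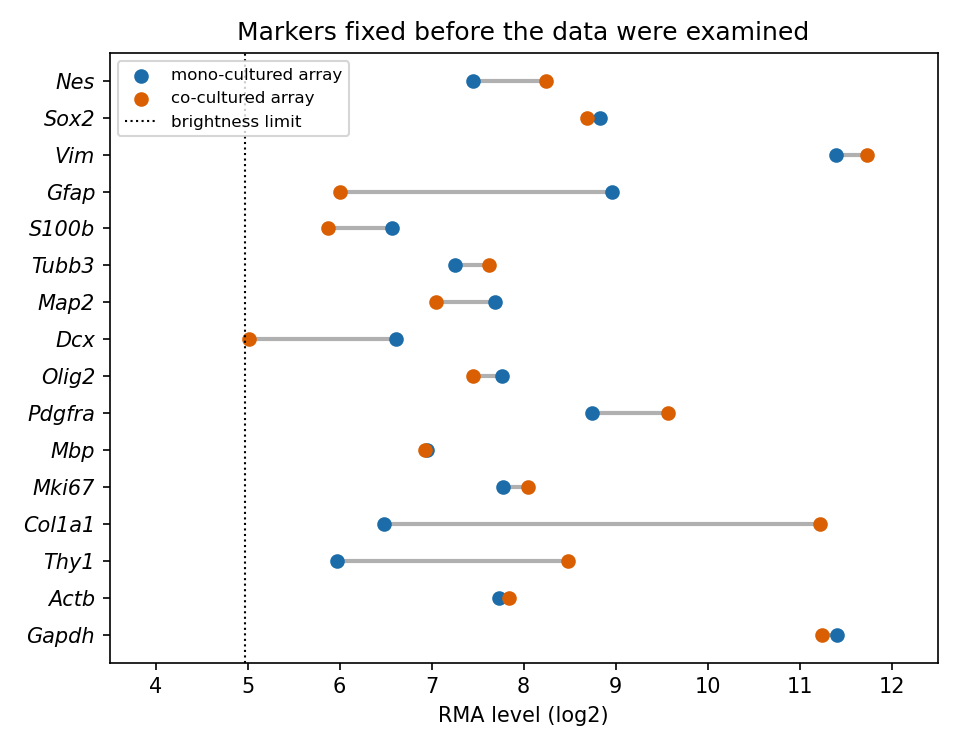
Levels of marker and housekeeping genes on the mono-cultured (blue) and co-cultured (orange) array as log2 RMA values, 1 array each; the dotted line is the median gene level of 4.97. Gfap is lower and Col1a1 and Thy1 are higher on the co-cultured array, while Sox2, Mbp, Actb and Gapdh lie close together.

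Cell cycle genes were slightly and evenly higher in co-culture. Of 33 kept members, 32 were higher and 0 passed 2-fold, with a median of 0.36 (interquartile range 0.24 to 0.52) and 0 of 10000 random lists as high. Rrm2, Kif23, Kif20a and Ccna2 differed by 0.96, 0.92, 0.85 and 0.79, and Mki67, the standard proliferation marker, by 0.27. These genes were dim, with 9 of 33 above 6.64 in co-culture and 3 in mono-culture. The central 95% of positive control probe sets lay between -1.15 and 0.61. The first 4 named genes lie above that range, but they were picked for the largest differences of the list. The upper quartile of the list, 0.52, lies inside the range. Genes of cell cycle arrest and the p53 response did not stand apart (20 kept, median -0.05, percentile 49.27, and -0.10 to 0.15 under the alternatives): Plk2 differed by 2.57, Pmaip1 by 1.49, Sesn2 by 0.83 and Cdkn1c by -1.22.

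Among signalling pathways, 7 of 25 TGF-beta and BMP genes were at least 2-fold higher and 0 lower (median 0.47, 0 of 10000 as high, 0.19 over the 18 members that reached 4.97 on both arrays, mean 1.01), led by Grem1, Tgfbi, Ccn2 (3.47) and Ltbp1 (3.23). In the Wnt list 6 of 21 were at least 2-fold higher and 1 lower (median 0.34, percentile 99.96). With dim levels raised to 4.97 this median was 0.15, over the 11 members that reached the 75th percentile it was 0.93, and the mean was 0.61. The Wnt antagonists Sfrp1 and Sfrp2 differed by 3.44 and 1.74, the receptor Fzd1 by 1.95 and the agonist Rspo1 by 1.78. In the Hedgehog list 3 of 12 were at least 2-fold higher, the co-receptors Boc (2.18), Gas1 (1.42) and Cdon (1.12), and the antagonist Hhip differed by 0.60 (median 0.50, percentile 99.99, and 1.12 over the 5 members that reached the 75th percentile). The Notch list did not stand apart (19 kept, median -0.14, percentile 23.94, mean 0.06), although its median was 0.39, at percentile 98.47, over the 7 members that reached the 75th percentile, and Hes1, the ligand Jag1 (1.66) and Notch2 (1.15) were at least 2-fold higher and Mfng (-1.32) lower. Of 18 neurotrophic factors and receptors, 4 were at least 2-fold higher, among them Ngfr and Hgf (2.10), and 3 lower, among them Ntrk2 (-1.86) and Fgf2 (-1.71). Their median of 0.17 lay at percentile 97.42, just inside the upper limit, and passed it under 9 of 11 alternatives, with medians of 0.15 to 0.28, and the mean of 0.29 lay inside, at percentile 95.73.

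Immediate early and serum response genes were higher, with 15 of 27 at least 2-fold higher and 0 lower (median 1.17, 0 of 10000 as high). Of the 27 genes 7 also stand on another list, Acta2 and Ccn2 among them. Without shared members, an alternative chosen after seeing the data, the median was 0.82, at percentile 100.0. Besides Acta2 and Ccn2, the phosphatase gene Dusp1 was 9.39 against 6.60 and the matricellular gene Ccn1 was 10.05 against 7.38. Genes of this kind are also known to be induced when cells are dissociated. Heat shock and oxidative stress genes, chosen as a list for stress from dissociation and sorting, did not stand apart (18 kept, median -0.13, percentile 20.78, mean -0.34, percentile 4.02), with Hmox1 at -1.73, Hspb1 at -1.01, Mt1 at -0.90 and Hspa1a at -0.73. Genes of the unfolded protein and amino acid responses had 4 of 26 at least 2-fold higher (median 0.23, percentile 99.93, and 0.15 without members shared with other lists): Chac1 (1.71), Slc7a5 (1.14), Asns (1.05) and Atf3 (1.04). Adhesion and junction genes had 6 of 23 at least 2-fold higher and 3 lower (median 0.23, percentile 99.54), with Itga1 at 2.17, Cdh11 at 1.91 and Nrcam at -2.14 beside L1cam. Their mean was 0.43, and their median without members shared with other lists was 0.14, at percentile 93.81, and over the 17 members that reached the 75th percentile 0.19, at percentile 97.27.

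Metabolic genes differed by less than 2-fold in most cases. Sterol synthesis genes were higher in 18 of 19 cases (median 0.37, 0 of 10000 as high), with Idi1, Sqle, Fdft1 and Hsd17b7 at 1.29, 1.16, 0.98 and 0.89. Oxidative phosphorylation genes were lower in 26 of 28 (median -0.35, percentile 0.01), with Ndufa1, Sdha, Ndufa2 and Atp5po between -0.72 and -0.60. Ribosomal protein genes were lower in 28 of 29 (median -0.31, percentile 0.43), with Rps14, Rps19, Rpl7a and Rps9 between -0.68 and -0.45, and probes of this family can also bind near-identical pseudogene transcripts. Both lists lay inside the random range when the mean replaced the median, at percentiles 2.70 and 3.25, as did ribosomal protein genes with 1 probe set (percentile 4.15), and the positive controls had a median difference of -0.16. Glycolysis and hypoxia genes had 6 of 27 at least 2-fold lower and 0 higher, with the oxygen sensor Egln3 at -2.56, Pfkfb3 at -1.61, Hk2 at -1.35 and the glucose transporter Slc2a1 at -1.28. Their median of -0.22 lay inside the random range, at percentile 4.07, and their mean of -0.44 outside it, at percentile 0.58, as was the median under quantile normalization (percentile 2.17) and without shared members (percentile 0.93). Actb differed by 0.11, and Gapdh by -0.17 as deposited and by -0.01 under loess scaling.

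**Figure D3:**
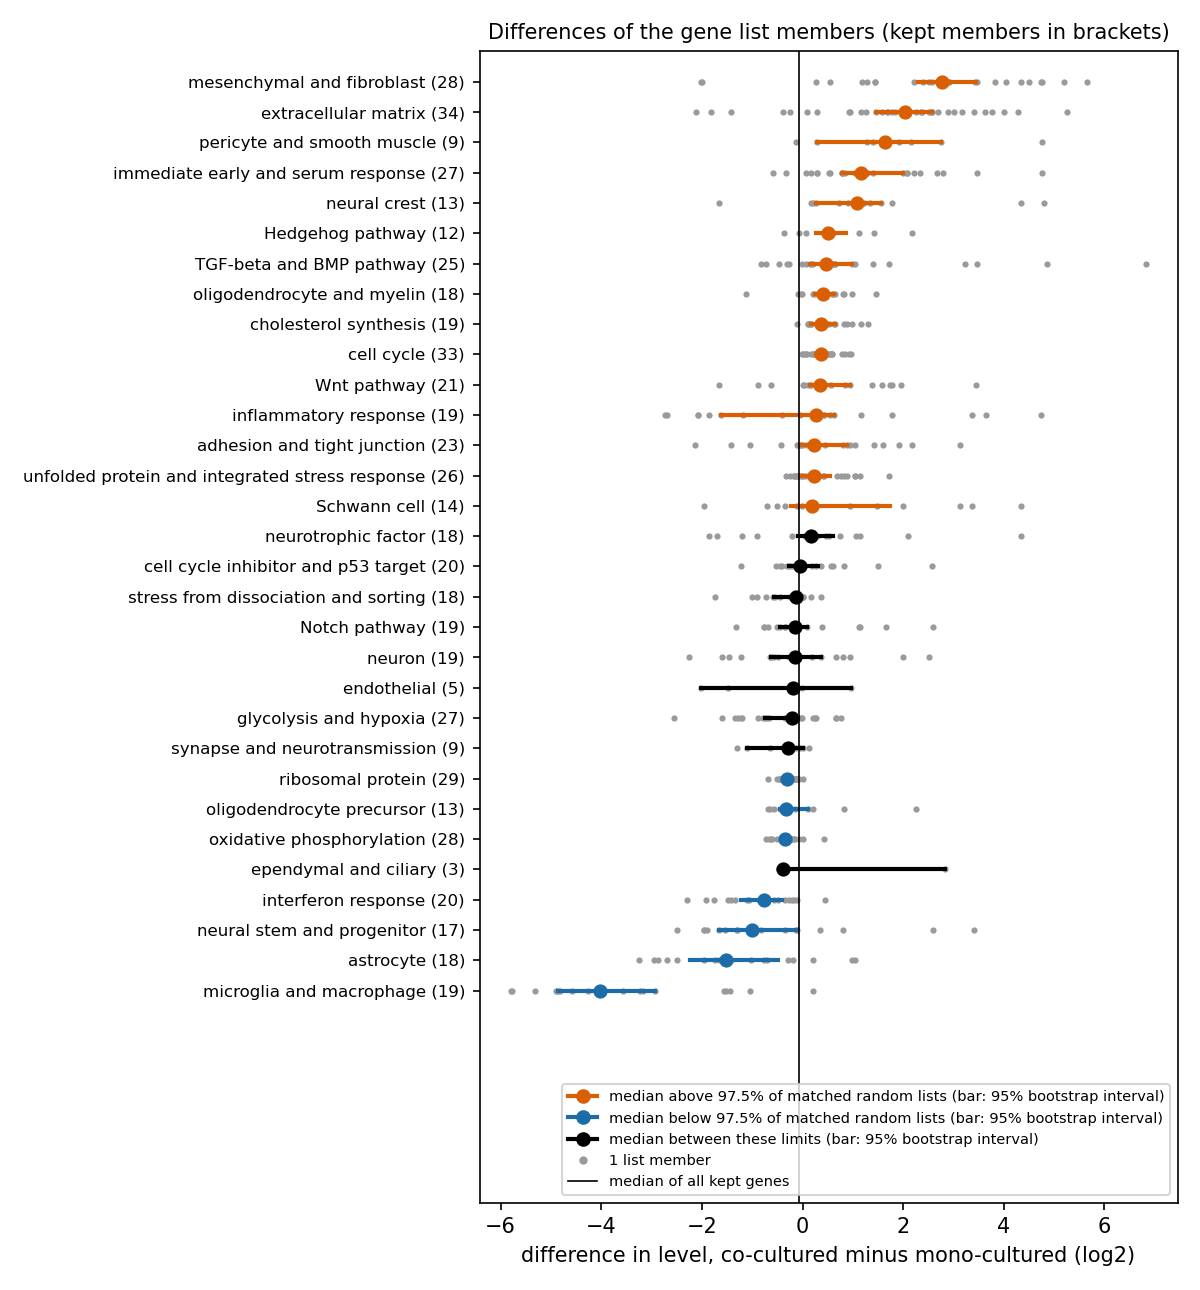
Differences of the members of the 31 gene lists (grey points, log2, co-cultured minus mono-cultured) with the list median (large point) and its 95% bootstrap interval over members (bar, which does not cover the spread between cultures); colours mark medians outside the central 95% of 10000 matched random lists. Mesenchymal genes have the highest median, 2.78, and microglia genes the lowest, -4.02.

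Of the 146 genes named by rule, 31 had levels below 6.64 on both arrays, so that their differences lie between levels in the range of the negative controls. They are Emx2, Dcx, Nlgn1, Gad1, Cplx2, Opalin, Snai1, Cdh19, Pecam1, Cdh5, Ramp2, Ttr, Foxj1, Kif23, Kif20a, Pmaip1, Mfng, Hhip, Hgf, Mx1, Oasl, Irf7, Il6, Hsd17b7, Ndufa1, Ndufa2, Hspb1, Hspa1a, Itga1, Pax6 and S100b.

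Of the 31 lists, 15 lay above the range of matched random lists, 7 below and 9 inside, where 1.55 outside would be expected if members were random genes. The percentiles describe this pair of arrays, since members of a list share regulation and no second culture was measured. The mono-cultured sample is not stated to have passed through the sorter or to have been kept in the serum-containing medium of the co-culture, so sorting and medium cannot be separated from the presence of EMSCs.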

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

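The tests on microglia genes and on astrocyte and myelin genes were chosen only after those results were seen, and the tests on mesenchymal genes were set beforehand. Scaling tests were also set beforehand for the cell cycle list, whose median was 0.37, 0.43 and 0.43 under median centring, quantile and loess scaling and stood apart under each, and for the neuron list, which stood apart under none of them. These scalings shifted the median difference of kept genes by only 0.01 to 0.06, so both outcomes test little. Outside the named genes, 243 unnamed transcript clusters at or above the brightness limit were at least 2-fold higher in co-culture and 321 at least 2-fold lower, of 9269, with differences up to 5.83 and down to -6.60. Together these are 6.1% of the bright unnamed clusters, against 10.6% of the kept genes. The unnamed clusters are listed because the named genes leave them out.

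Mesenchymal genes were higher in the co-cultured array. The list median nearest 0 under median centring, quantile and loess scaling was 2.79. This tests little because these scalings shifted the median difference of kept genes by only 0.01 to 0.06. A scaling fault would move genes of like level alike, however, and matched random lists had a median of -0.06 with 0 of 10000 as high. RNA of feeder cells that passed the sort is a candidate explanation, because 92.86% of the kept members were higher, as carry-over would give, and Col1a1 and Thbs1 reached 11.23 and 10.87, although the sort served to separate the NSCs from the fluorescent feeder cells. The share does not single out feeder cells, since 6 of the 28 members exceeded the negative control level of 6.64 in mono-culture too and 7 stand on another list, and Eng (-2.02) and Nt5e (5.73 against 7.73) were lower in co-culture. Expression of these genes by the NSCs themselves would give the same share, and it and an effect of serum were not tested and stay open.

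Microglia genes were lower in the co-cultured array. The list median nearest 0 under the 3 scalings was -3.95, which tests little, as for the mesenchymal genes. Matched random lists, which a scaling fault would move alike, had a median of -0.06 with 0 of 10000 as low. RNA of microglia or macrophages present in the mono-cultured sample is a candidate explanation that stays open: 94.74% of the kept members were lower, but this share restates the pattern, and any cause of lower microglia gene levels would give it. In mono-culture 15 of the 19 kept members exceeded 6.64, with C1qb, Cd68 and C1qa at 10.45, 10.53 and 10.39, and in co-culture 1 did, while 0 stand on another list. Loss of such cells in the sort or beside EMSCs was not tested, since sort and co-culture go together in this design.

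Astrocyte genes were lower while myelin genes were not. Dilution of neural RNA by feeder RNA would lower both alike if feeder cells lack both sets of transcripts. Feeder cells were not measured alone, so this premise was not tested. The astrocyte minus the myelin list median was -1.93 (95% bootstrap interval over genes -2.56 to -0.95), which argues against dilution as the whole cause only if the premise holds. Under the scalings the difference nearest 0 was -1.92. This tests little, since a shift common to both lists cancels in the difference. Of 10000 random lists of like level 0 were as low as the astrocyte list and 1 as high as the myelin list. A scaling fault would move genes of like level alike, so these random lists argue against it. A difference in the cell types that formed in co-culture, in medium or in sorting stays open and was not tested.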

How the results depend on the processing

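Raising dim levels to the limit and leaving out shared list members were chosen after seeing the data. No paired analysis was possible because each condition has 1 sample, and no replicate could be left out. The counts of 597 higher and 657 lower genes became 313 and 303 where both values had to reach the limit, 1095 and 1347 at 1.5-fold, and 213 and 226 at 4-fold; 16 of 22 alternative counts were within 1.5 times. Each of these follows from the construction of the setting. The scalings shifted the median of kept genes by 0.01 to 0.06. Of 338 alternative list values, 335 lay within the list's bootstrap interval and 3 outside it. This count does not show stability, since some intervals are wide, such as -2.02 to 0.96 for the endothelial list. Some settings also leave the members of a list unchanged. The Schwann cell median turned from 0.19 to -0.11 without members shared with another list. Over genes at or above the 75th percentile the Notch median was 0.39 and the Hedgehog median 1.12, and the TGF-beta and BMP median of 0.47 was 0.19 where both values had to reach the limit and its mean 1.01. Without the filter the pericyte median went from 1.64 to 0.37. Of 22 lists that stood apart, 11 had at least 1 alternative value more than 1.5 times away. For these list values the cause was not tested. Of 31 lists, 20 stayed on the same side of the percentile limits in every setting run, and 11 crossed in at least 1: neuron, oligodendrocyte precursor, Schwann cell, ependymal, Notch, neurotrophic factor, inflammatory, glycolysis, oxidative phosphorylation, ribosomal protein and adhesion. The ependymal list had too few members under the filters at the 75th percentile and on both values, and the endothelial list under the filter at the 75th percentile. Of 864 alternative values of named genes, 823 moved by less than the SD of positive controls, and 40 of the other 41 came nearer to 0 when dim levels were raised to the limit. The rules for several probe sets cannot move genes with 1 probe set, and the scalings shifted the median difference of kept genes by only 0.01 to 0.06. The count of 823 therefore says little about stability. Dim levels limit the folds: 1604 kept genes had their lower value below 4.97 and 8340 below the negative control level of 6.64.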

Other observations

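Gene families were also picked by symbol after the values were seen. They are no independent support for the lists above, since some of their genes, such as Col1a1 and Ctss, stand on those lists. Of 33 Hox genes on the array, which pattern the body axis behind the forebrain and midbrain, 33 had a higher value in co-culture, with a median difference of 0.69 (0.70 under median centring and 0.64 under quantile scaling). Their levels, up to 6.36 for Hoxa6 in co-culture, all lie below the negative control level of 6.64. The 12 kept Hox genes had mono-cultured levels below 4.97, so the filter fixed their direction. Among 61 genes on the array of other homeobox and paired box families (among them Pax, Nkx, Lhx, Irx, Dlx and Pou genes) the median was 0.10, with 37 higher and 23 lower. Among the 32 kept the median was 0.09, with 18 higher and 14 lower. Of 42 collagen genes on the array, 42 had a higher value in co-culture, with a median of 0.46, and the 32 kept had a median of 1.27, with 18 at least 2-fold higher. Of 18 Adamts protease genes on the array, 16 had a higher value (median 0.39). The orphan nuclear receptors Nr4a1, Nr4a2 and Nr4a3, which respond quickly to stimuli, differed by 2.09, 2.93 and 1.57. Of 5 kept insulin-like growth factor binding proteins, Igfbp4, Igfbp5 and Igfbp7 differed by 2.08, 2.00 and 1.95, while Igfbp2 differed by -1.56.

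Lysosomal cathepsin genes went both ways. Over the 18 on the array the median was -0.40, with 6 higher and 12 lower. Of 11 kept, 7 were at least 2-fold lower in co-culture, including Ctss (-4.87), Ctsz (-3.67), Ctsc (-2.16) and Ctsd (-1.79), and Ctsl lay within 2-fold at 0.15. Ctsk, which fibroblasts and osteoclasts use to degrade collagen, was higher by 2.15. All 6 genes on the array with symbols that begin with Fcgr, Fcgrt (-1.42) among them, were at least 2-fold lower, with a median of -3.68. Of 12 toll-like receptor genes 10 had a lower value (median -1.30). The directions of the Hox, collagen, Adamts, cathepsin, Fcgr and toll-like receptor medians over all members on the array were the same under median centring and quantile scaling. This tests little, since these scalings shifted the median difference of kept genes by only 0.01 and 0.05. Of 8 kept amino acid transporters of the Slc38a family, 2 were at least 2-fold higher and 2 at least 2-fold lower: Slc38a4 and Slc38a2 differed by 3.03 and 2.23 and Slc38a3, a glutamine transporter of astrocytes, by -1.48 and Slc38a6 by -1.06.

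The control RNAs added during labelling and hybridisation were dimmer on the co-cultured array in 7 of 8 cases. The differences were -0.23, -0.55, -0.66 and -0.85 for the dap, lys, phe and thr controls, and -0.52, -0.64, -0.07 and 0.01 for bioB, bioC, bioD and cre.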
